A study of Rattus norvegicus with 13 samples.

How the data were processed

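The data were 13 single-colour cDNA arrays of total RNA from the septal coronary arteries of F344 rats, an inbred rat strain widely used in research on ageing. Per the labels, 6 arrays came from rats of 26 months (aged) and 7 from rats of 3 months (young). The group of each array was taken from its description and the replicate number from its title. The labels do not say whether each array was made from a separate animal, so the p-values measure the spread between these arrays, which may be partly technical.

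The deposited table gives, for each of 100 probes, a linear ratio to the array's own beta-actin signal. This was read from the values: the mean of the 2 deposited beta-actin (Actb) spots was 1 on each of the 13 arrays, which was checked on the file. The ratios are rounded to 2 decimals and run from 0.01 to 4.51. Scanner, membrane, background correction and software are not given in the sources used here. No deposited value was 0 or negative, and 426 of the 1248 cells of the gene probes (34.1%) were blank. Why a cell is blank is not given in the sources used here. The rounding and the blanks weigh most on dim probes, where a step of 0.01 is a large part of the ratio. Since each ratio carries the beta-actin signal of its array in the denominator, an error in that signal moves every gene of the array together.

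Gene names came from the platform annotation table, in which 91 probes had 1 gene symbol, none had several, and 9 gene probes were not listed and are given by probe number. None of the annotation's gene IDs (0 matched) and none of its accessions (0 matched) occurred in the rat gene table used here, while 87 of its 90 distinct symbols were also rat symbols. The organism of the probe sequences is therefore not settled here, and a cross-species difference in sequence would alter the level of a probe on all arrays alike. Symbols are printed as the annotation gives them, with no coordinates. No column of another sample was present.

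The test of genes used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on log2 ratios, with no pseudocount, no further normalization and all 13 arrays in a fit with age as its only factor. The rule for scaling, the test, the gene lists and the rule for named genes were fixed before the data were examined. The scaling rule kept the ratios as deposited because a reference gene was constant over the arrays. The 4 spots of reference genes (Actb in 2 spots, Gapdh and Rpl13a) stayed out of the test. Blanks stayed missing, and a probe needed at least 3 values in each group, which left 70 of the 96 gene probes (7 of them unnamed). P-values were adjusted by the Benjamini-Hochberg method over these 70, with a threshold of 0.05. Fold changes are 2 to the power of the difference of mean log2 ratios over measured arrays, and counts of higher and lower genes go by the same difference. On simulated data with the means, spreads and blanks of these 70 genes, in 50 sets with 14 changed genes each, the fit recovered 36.0% of the 4-fold changes and 5.14% of the 2-fold changes, with 4.64% false calls.

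Of the 28 gene lists, 10 had at least 3 tested genes and were tested with limma's fry, which asks whether the genes of a list move, on balance, one way. Because fry takes no blanks, they were set to the smallest deposited ratio, 0.01, for this test only. That step was not foreseen, and an exact permutation test on the mean of each list's measured genes was added beside it. In 50 simulated sets the fry step called 3.8% of unchanged lists at an unadjusted p under 0.05 and recovered a 2-fold rise of the caspase list in 100% of the sets. That share need not hold for the real arrays, where a level shared by the genes of an array varied widely (see Results). A list that did not pass may therefore still have shifted. Single values of an array (the level of the 15 gene probes measured on all 13 arrays, the mean of Gapdh and Rpl13a, the number of blanks) were compared with exact two-sided permutation tests over all splits of the arrays. The levels of same-numbered arrays were correlated, with exact tests over all pairings, a test chosen after the levels were seen.

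The genes named in the text follow this rule: every gene past the threshold, then the genes of smallest p up to 20 in all, a preset group of cytokine and apoptosis genes where measured (Tnf, Casp8, Casp9, Bcl2, Bcl2l1, Fas and Fasl), and the reference genes. Genes outside it are named as members of a list or, where said, after their values were seen. Alternatives covered other centring and scaling, a pseudocount of 0.02, a filter at the 25th percentile of gene means, other tests, the replicate number as a block, and each array left out in turn. The block used the 6 same-numbered pairs and so left out young replicate 7. The deposited table could not be set against unprocessed signals, which were not analysed here.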

Results

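Expression of apoptosis-related genes was measured on 13 arrays of septal coronary artery RNA, 6 from aged F344 rats (26 months) and 7 from young ones (3 months). The labels add that a TUNEL assay and a test for DNA fragmentation had shown more endothelial cell death in the older vessels. The array carried 96 gene probes, among them members of the TNF, Bcl-2, caspase and TRAF families, and spots of 3 reference genes. Each value is a ratio to the beta-actin signal of the same array. Between 52 and 80 gene probes had a value on an array, and 29.5 ± 8.7 were blank on the aged and 35.6 ± 7.8 on the young arrays (SD, n = 6 and 7). The number of arrays and the rounding of the ratios limit the precision, and the signal over background is unknown.

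The comparison of the age groups asks which of these genes differ in expression between old and young coronary arteries. Tnf, which encodes the proinflammatory cytokine tumour necrosis factor, was the gene that rose with age. Its ratio was 0.223 ± 0.050 in aged arteries (SD, n = 6) and 0.062 ± 0.036 in young arteries (SD, n = 6, with 1 further array blank), a 4.18-fold difference (log2 difference 2.06, SE 0.51, adjusted p = 0.031 by limma). Every aged array (0.18 to 0.3) lay above every young array with a value (0.02 to 0.12). The young ratios are dim, near the smallest deposited ratio of 0.01, so the rounding to 2 decimals makes the fold imprecise. No gene fell past the threshold. Of the 70 genes tested, 40 had a higher and 30 a lower mean log2 ratio in aged arteries, and 4 had an unadjusted p under 0.05. Each array was also centred on the mean log2 ratio of its reference genes, Actb, Gapdh and Rpl13a. Since Actb is the denominator itself, this takes out less than the shift of Gapdh and Rpl13a alone. With this centring 29 genes had a higher and 41 a lower mean log2 ratio, and Tnf no longer passed (log2 difference 1.80, adjusted p = 0.076 by limma). Centring each array on the 15 probes measured on every array left 13 genes higher and 57 lower and brought Tnf to 1.25 (adjusted p = 0.31 by limma). With blanks set to 0.01, the smallest deposited ratio, the Tnf difference was 2.40 (adjusted p = 0.099 by limma), and with its 1 blank set to 0.3, the highest Tnf ratio of any array, it was 1.70 (adjusted p = 0.23 by limma).

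The Tnf difference kept its size, 1.79 to 2.30 on the log2 scale, when any 1 array was left out, but its adjusted p did not stay below the threshold in each case. It was 0.077, 0.067, 0.094, 0.108 and 0.055 by limma without aged replicates 1, 2, 3, 4 and 6, and 0.119, 0.058 and 0.162 without young replicates 3, 5 and 6. It stayed under 0.05 without each of the other 5 arrays. Across genes, an exact permutation test gave Tnf the smallest p that its 12 measured arrays allow, 0.0022, and an adjusted p of 0.076. It called no gene. A lone gene at that p does not pass the adjustment over 70 genes, so this test could not call Tnf by itself.

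Casp9, the initiator caspase of the mitochondrial death pathway, and Lta, the TNF-family cytokine lymphotoxin alpha, had the next smallest p-values and did not pass the adjustment. Casp9 averaged 0.245 ± 0.126 in aged and 0.093 ± 0.070 in young arteries (SD, n = 6 and 7), 3.06-fold apart (log2 difference 1.61, SE 0.54, adjusted p = 0.23 by limma). Centring on the 15 probes measured on every array brought the Casp9 difference to 0.81 (adjusted p = 0.33 by limma). Lta averaged 2.90 ± 0.66 in aged and 1.40 ± 0.52 in young arteries (SD, n = 6 and 7), 2.21-fold apart (log2 difference 1.15, SE 0.46, adjusted p = 0.47 by limma). The Lta ratios did not overlap, with 2.01 the lowest aged value and 1.98 the highest young value (exact permutation p = 0.0012, adjusted p = 0.076). Fitted on linear ratios without a log, the Lta difference did pass (adjusted p = 0.015 by limma), while its log2 difference was 0.54 with quantile normalization (adjusted p = 0.90) and 0.34 with centring on the 15 probes measured on every array (adjusted p = 0.58).

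**Figure D1:**
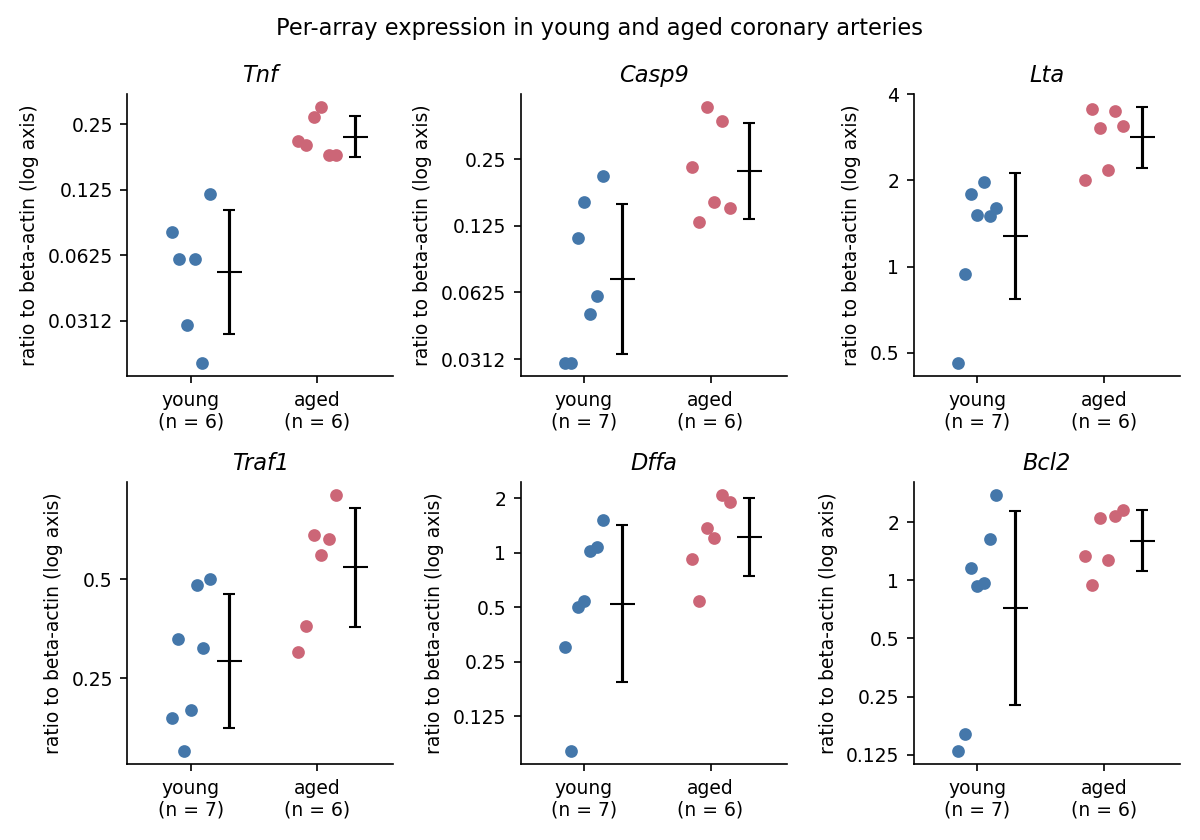
Ratio to beta-actin on each array (log2-spaced vertical axis) for 6 genes in young and aged arteries; each point is 1 array, and the bar beside the points is the mean ± SD of the log2 ratios. The Tnf points of the groups do not overlap (0.02 to 0.12 against 0.18 to 0.3), nor do those of Lta, while Casp9, Traf1, Dffa and Bcl2 overlap.

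Higher means in aged arteries, without passing the threshold, were also found for Dffa, Gadd45a, Bcl2, Traf1, Casp2, Tnfrsf21 and Bik. Dffa, the inhibitor and chaperone of the nuclease that cuts DNA in apoptosis, averaged 1.34 ± 0.58 against 0.72 ± 0.50 (SD, n = 6 and 7). Gadd45a, a growth arrest and DNA damage gene, averaged 2.48 ± 1.23 against 1.47 ± 0.96. Bcl2, which protects mitochondria from permeabilization, averaged 1.69 ± 0.57 against 1.11 ± 0.91. Traf1, a signalling adaptor of TNF receptors, averaged 0.582 ± 0.222 against 0.309 ± 0.140. Casp2 averaged 0.603 ± 0.169 against 0.374 ± 0.257. Tnfrsf21, a death receptor, averaged 1.32 ± 0.30 against 0.83 ± 0.37. Bik, a BH3-only killer protein, averaged 1.79 ± 0.69 against 1.22 ± 0.81. The log2 differences of these 7 genes ran from 0.78 to 1.26, with adjusted p-values of 0.64 to 0.72 by limma. With quantile normalization they ran from 0.08 (Bik) to 0.64 (Bcl2). All 7 are among the 15 probes measured on every array, which were higher together by 0.80. Without young replicate 1 the differences of Gadd45a, Bcl2 and Bik were 0.70, 0.75 and 0.47, and that of Dffa was 0.77 without young replicate 2. Without both arrays Gadd45a, Bcl2, Bik, Dffa and Casp2 differed by 0.20, 0.23, 0.24, 0.52 and 0.51, Traf1 by 0.88 and Tnfrsf21 by 0.91. Tnfrsf1b, a TNF receptor named here after its values were seen, averaged 3.19 ± 0.95 in aged and 2.77 ± 1.04 in young arteries (log2 difference 0.30, adjusted p = 0.91 by limma).

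The named genes with lower log2 means in aged arteries had ratios of at most 0.44 on any array. Cd27, a TNF receptor of lymphocytes, averaged 0.054 ± 0.022 on 5 aged arrays and 0.150 ± 0.080 on 3 young arrays (log2 difference -1.45, SE 0.68, unadjusted p = 0.046, adjusted p = 0.64 by limma), and its direction turned, to 0.31, with blanks at 0.01. Pycard, an adaptor of inflammatory caspases, averaged 0.108 ± 0.088 on 6 aged and 0.240 ± 0.183 on 5 young arrays (log2 difference -1.30, SE 0.74, adjusted p = 0.64 by limma), with a difference of -0.73 without aged replicate 2 and -0.11 with blanks at 0.01. The inhibitors of apoptosis Birc3, Cflar and Naip5 had log2 differences of -1.01, -0.98 and -0.94, and Bad, Tnfrsf8 and Fasl of -0.96, -0.84 and -0.79, with adjusted p-values of 0.72 to 0.86 by limma. These 6 genes were each blank on at least 3 of the 13 arrays, Cflar turned to 0.065 with blanks at 0.01, and Bad stood at -0.26 without aged replicate 1. Among the named genes left, Casp8, the initiator caspase of death receptors, averaged 0.187 ± 0.087 in aged and 0.199 ± 0.135 in young arteries (log2 difference 0.03, 95% interval -1.04 to 1.11). Casp6 had a log2 difference of 0.86, and the unnamed probes 78 and 2 had 0.85 and 0.67, each with an adjusted p of 0.72 or 0.86 by limma. Casp6 stood at 0.19 without young replicate 2, probe 78 at 0.51 without young replicate 1, and probe 2 at 0.33 without aged replicate 1. Bcl2l1 (0.043 on 3 aged and 0.08 on 2 young arrays) and Fas (0.065 on 4 aged and 0.035 on 2 young arrays) had too few values for a test.

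**Figure D2:**
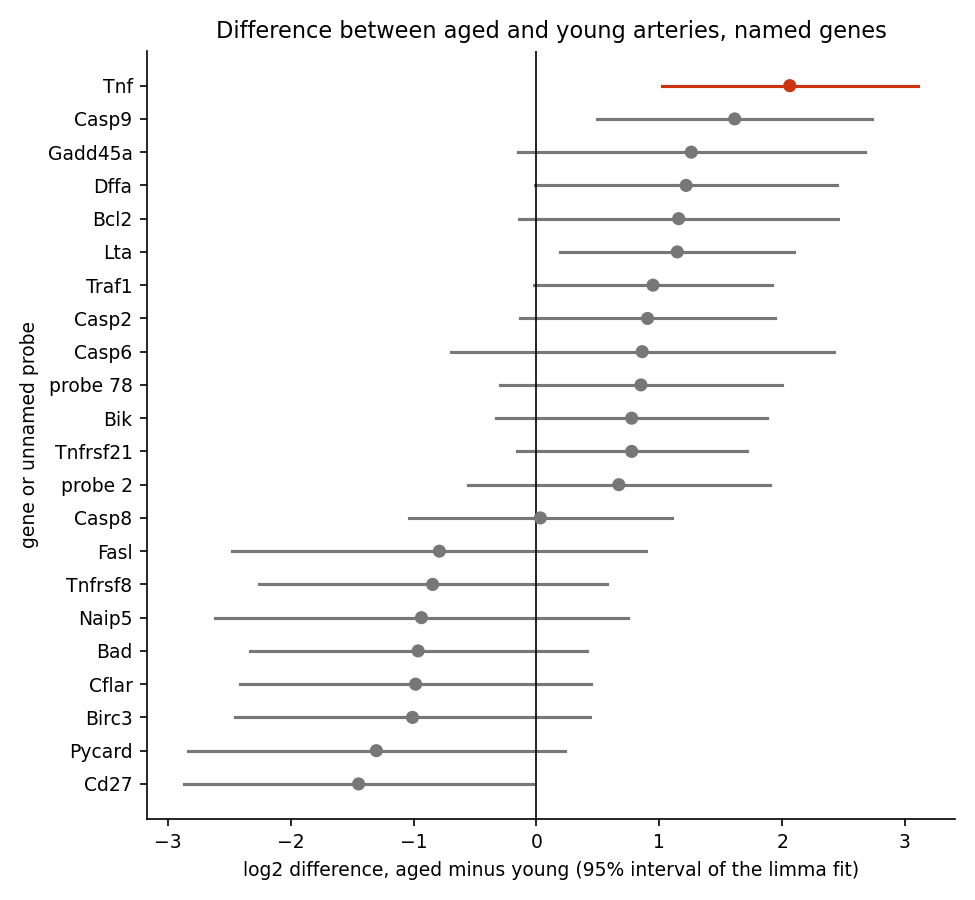
Log2 difference between aged and young arteries (horizontal axis) with its 95% interval for the 22 named genes and probes that were tested. Tnf (red) passed the adjusted threshold of 0.05. The other intervals (grey) belong to genes that did not, among them Casp9 at 1.61 and Lta at 1.15, whose unadjusted intervals lie above 0. That of Cd27, at -1.45, lies below 0 (-2.87 to -0.03).

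By gene list, the proinflammatory cytokines were higher on balance in aged arteries (fry adjusted p = 0.011 over 10 lists, mean log2 difference 0.99). Against the other genes of the array the list passed camera with a preset correlation (adjusted p = 0.046), and not with an estimated correlation (adjusted p = 0.16). On this array the list held 3 genes, Tnf, Lta and Ltb, so its shift rests largely on Tnf and Lta. Ltb had a log2 difference of -0.24 over its measured arrays, but with blanks at 0.01, as fry used them, 3 of 3 genes were higher and the mean was 1.24. Over all genes tested 1 of the 3 rose, and 2 of the 3, Tnf and Lta, passed when adjusted over the list alone. The exact permutation test on the mean of measured genes gave an adjusted p of 0.012. Its fry adjusted p was 0.0054 to 0.046 with 1 array left out, and 0.53 with each array centred on the 15 probes measured everywhere, where the mean difference was 0.10.

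The remaining lists did not pass fry, with adjusted p-values from 0.29 to 0.76. Of the 11 TNF superfamily ligands tested, 1 (Tnf) rose, both over all genes and adjusted over the list alone, and 6 had a higher mean log2 ratio in aged arteries, against 5 after centring on the reference genes and 3 after centring on the 15 probes. In each of the 8 lists left to describe, 0 genes passed limma, over all genes and adjusted over the list alone alike, with 1 caspase (Casp9) and 1 TNF receptor (Cd27) at an unadjusted p under 0.05. Among 8 caspases, 7 had a higher mean log2 ratio in aged arteries, but 3 did after centring on the reference genes and 2 after centring on the 15 probes measured on every array. Without young replicate 7 the caspase list passed (fry adjusted p = 0.0095). That array had the highest level of the young arrays (0.12 for the 15 probes measured on every array). The caspases measured on every array, Casp8, Casp2 and Casp9, had their highest young ratios there (0.47, 0.86 and 0.21). On the other young arrays they were at most 0.22, 0.5 and 0.16. Of 5 anti-apoptotic Bcl-2 members 4 had a higher mean log2 ratio as deposited and 1 after centring on the 15 probes, and of 8 pro-apoptotic members 4 did as deposited and 1 after that centring. Of the 5 inhibitors of apoptosis 2 had a higher mean log2 ratio, Birc2 (0.37) and Birc6 (0.25), though their mean linear ratios were lower in aged arteries (0.0733 against 0.078 for Birc2 and 0.0733 against 0.098 for Birc6), and after centring on the 15 probes 0 were higher. They had a mean log2 difference of -0.46, which was negative under each scaling tried (-0.20 to -1.11). That list passed camera with the preset correlation (adjusted p = 0.046) but not with an estimated correlation (adjusted p = 0.16). TNF receptors (5 of 8 higher as deposited, 0 of 8 after centring on the 15 probes), TRAF members and adaptors (3 of 7, and 1 of 7), p53 and DNA damage genes (1 of 4 in both) and caspase activators (1 of 3 in both) had mean log2 differences of -0.02, 0.01, 0.05 and -0.11. For these 4 lists and the pro-apoptotic members, whose mean was -0.03, the sign of the mean, the median and the fry direction were not all alike.

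The reference genes and the overall level of the arrays were compared as checks on the denominator. Gapdh, a glycolytic enzyme, had a ratio to beta-actin of 0.732 ± 0.073 in aged and 0.654 ± 0.141 in young arteries, and Rpl13a, a ribosomal protein, had 0.227 ± 0.036 against 0.169 ± 0.074 (SD, n = 6 and 7). Neither differed alone (exact permutation p = 0.22 and 0.085, two-sided). Their mean log2 ratio was 0.36 higher in aged arteries (95% interval 0.03 to 0.68, exact permutation p = 0.041). Leaving out 1 array brought that p to between 0.052 and 0.080 in 9 of 13 cases, namely without aged replicates 1, 2, 4, 5 or 6 or young replicates 1, 2, 3 or 6, with differences of 0.29 to 0.37. The sign turned with quantile normalization (-0.10) and with centring on the 15 probes (-0.45).

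The 15 gene probes measured on all 13 arrays were, on average, 0.80 higher on the log2 scale in aged arteries (95% interval -0.02 to 1.63, exact permutation p = 0.051), and 14 of the 15 had a higher mean log2 ratio. The exact permutation p was 0.043, 0.048, 0.048 and 0.0087 without aged replicate 1 and young replicates 5, 6 and 7. The other 55 tested probes were split, 26 higher and 29 lower. The levels of young replicates 1 to 7 were -2.50, -1.76, -1.08, -1.02, -0.57, -0.59 and 0.12, and those of aged replicates 1 to 6 were -0.68, -0.56, -0.12, -0.44, 0.15 and 0.12. The levels of same-numbered arrays were correlated across the groups (Pearson r = 0.893, exact permutation p = 0.0069, and Spearman rho = 0.943, exact permutation p = 0.017, over 6 pairs); without the 2 pairs farthest from the median r was 0.796 (exact permutation p = 0.21). Without young replicates 1 and 2, the arrays of lowest level, the difference of level was 0.38 (95% interval -0.19 to 0.94, exact permutation p = 0.18), while Tnf remained the 1 gene past the threshold (log2 difference 2.26, adjusted p = 0.027 by limma) and the proinflammatory list kept a fry adjusted p of 0.029. The Tnf ratios of these 2 arrays, 0.08 and 0.06, were not low among the young arrays (0.02 to 0.12), so leaving them out could not shrink the Tnf difference. Centring on these 15 probes moved the median difference of the tested genes from 0.06 to -0.69 (0.17 with median centring and -0.19 with reference centring). Of the 51 cell type markers fixed for cardiomyocytes, smooth muscle, endothelium, fibroblasts and leukocytes, 1 was on the array, Cd40, so the cell makeup of the dissected vessels was not compared.

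**Figure D3:**
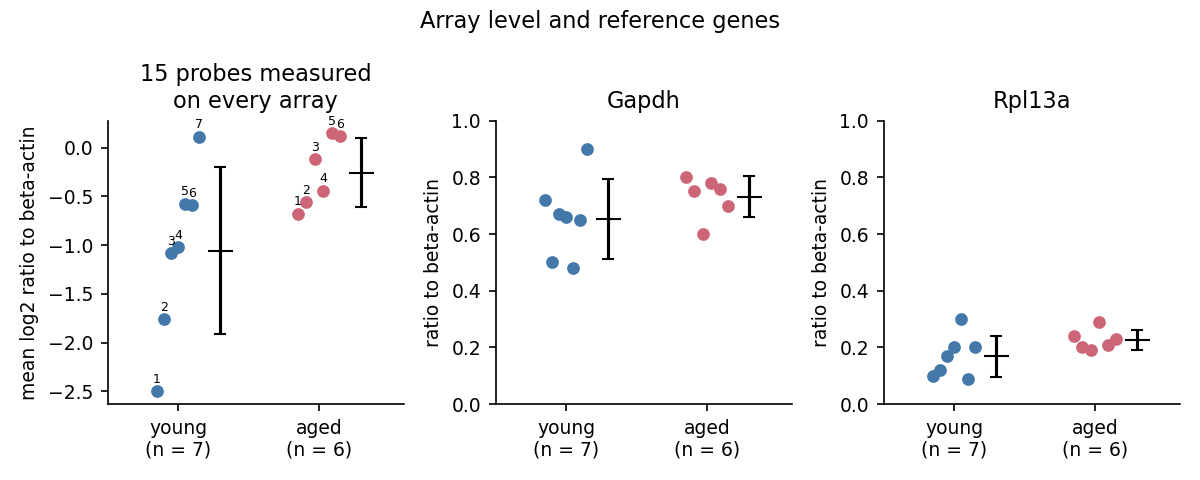
Mean log2 ratio to beta-actin of the 15 gene probes measured on every array (left) and the linear ratios of Gapdh and Rpl13a (middle and right) on each array; bars are mean ± SD, and the numbers beside the points are replicate numbers. Young replicates 1 and 2, at -2.50 and -1.76, lie below the others in level. Their Gapdh ratios (0.72 and 0.5) and Rpl13a ratios (0.1 and 0.12) lie within the range of the other young arrays (0.48 to 0.9 and 0.09 to 0.3). For Rpl13a this holds only through young replicate 6, at 0.09, and the lowest aged Rpl13a ratio is 0.19.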

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

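The tests of Tnf and of the array level in this part were chosen after those results had been seen; the count of splits was planned before its result was seen. Casp8 in young replicate 7, at a ratio of 0.47, stood apart from the other young arrays, the next of which was 0.22, in a search of 46 groups of values in which chance marks about 1 in 20. Tnfsf12, a TNF-family ligand too sparse for the test, had a value on 4 aged arrays and on 0 young arrays (Fisher's exact p = 0.021, adjusted p = 1 over 96 probes).

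The higher Tnf ratio was weighed against the array-wide level, the low young arrays and the blanks. If Tnf rose relative to beta-actin only as the 15 probes measured everywhere did, centring on them would leave no Tnf difference. It was 1.25 (95% interval 0.06 to 2.44) against 2.06 (1.02 to 3.11) before. The call ended (adjusted p = 0.31 by limma), as the difference shrank while its interval stayed about as wide. That interval is close to 0 and is not adjusted for Tnf having the smallest p of the 70 genes. Tnf is also a dim probe outside the 15, and the other 55 tested probes were split (26 higher and 29 lower). The centring therefore does not settle whether an array-wide rise accounts for the Tnf difference. Leaving out young replicates 1 and 2 gave 2.26 (1.13 to 3.40). Their Tnf ratios, 0.08 and 0.06, were not low among the young arrays (0.02 to 0.12), so this outcome was set by values already seen. It shows only that these 2 arrays do not make the Tnf difference. Setting the 1 blank of Tnf to 0.3, the highest Tnf ratio of any array, gave 1.70 (0.58 to 2.83), which argues against the blank as the whole cause. With the blank so filled the call ended (adjusted p = 0.23 by limma), as that value lowered the difference and widened the young spread. Of 100 splits of the arrays into 6 and 7, 4, the real one included, gave at least 1 gene past the threshold, a share under 0.05. But 1 other split called 7 genes, so a grouping other than by age can call more. This may point to a structure of the arrays, but no factor behind it was tested. A rise of Tnf expression with age stays a hypothesis, and the cells it would come from cannot be read from this array.

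The second pattern is the higher level of the 15 probes on aged arrays, 0.80 on the log2 scale. Without young replicates 1 and 2 it was 0.375 (95% interval -0.19 to 0.94), but those arrays were picked for their low ratios, so a smaller difference without them was bound to follow. The 4 same-numbered pairs without them also leave out young replicate 7, the young array of highest level. These pairs were all higher in the aged array (by 0.58 to 0.96, exact sign-flip p = 0.125, the smallest 4 pairs allow). They are too few to tell whether young replicates 1 and 2 alone make the pattern. The levels of same-numbered aged and young arrays also went together (Pearson r = 0.893 over 6 pairs). A factor shared by same-numbered arrays, such as the order or day of processing, may thus underlie part of the spread. The labels do not say what the numbers mark. Less beta-actin signal on the aged arrays could raise every gene, and Gapdh and Rpl13a were higher by 0.356. The other 55 tested probes did not rise as a set (26 higher and 29 lower, median -0.125, against 0.851 for the 15). Each of those probes was blank on some arrays, so their means rest on the measured arrays only. With blanks at the smallest deposited ratio, 46 of the 70 tested genes were higher, against 40 as deposited, and their median was 0.306, against 0.058. Both counts include the 15 complete probes, 14 of them higher, which have no blanks. The change in the count therefore lies in the other 55 probes, which were not summarized alone with filled blanks. The split of the 55 probes therefore does not decide on the beta-actin signal. The 15 probes exceeded Gapdh and Rpl13a by 0.447 with an interval of -0.29 to 1.18. Within same-numbered pairs, which leave out young replicate 7, they did so by 0.57 (0.11 to 1.03, 5 of 6 pairs, exact sign-flip p = 0.0625). Over complete pairs the mean is the same with or without pairing, so the step from 0.447 to 0.57 comes from leaving out that array. The explanations cannot be told apart from these values, and whether the numbers pair the arrays is open. A common effect of age on these genes remains open and was not tested apart from these.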

How the results depend on the processing

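Alternatives that set blanks to 0.01, kept only complete probes, centred on the 15 probes, set the Tnf blank to 0.3 or left out young replicates 1 and 2 together, the comparison of array level and its replicate block, that block for the reference genes, and the exact permutation test on list means were chosen after seeing the data. The count of 1 changed gene was 0 with centring on reference genes, the exact permutation test, the replicate block, blanks at 0.01, only complete probes (which leave Tnf out), centring on the 15 probes, or the Tnf blank at 0.3; it was 2 (Tnf and Lta) on linear values, and 0 to 1 with 1 array left out. These settings of 0 genes had 4, 6, 12, 2, 4, 10 and 4 genes at an unadjusted p under 0.05, in that order, all but the permutation test from limma. The replicate block tested 58 genes and the complete probes 15, against 70 in the others. With centring on the 15 probes, 57 of the 70 genes were lower in aged arteries. The gene was Tnf under each setting that called 1. The exact permutation test could not call Tnf by itself, whatever its values. The count of 1 shifted list was 2 with camera at the preset correlation, 0 with an estimated correlation, 3 with the replicate block (caspases and the p53 list added), 0 with centring on the 15 probes, and 1 to 2 with 1 array left out. The caspase list also passed without young replicate 7 and with no block (fry adjusted p = 0.0095). Whether the replicate numbers pair the arrays is not given by the labels, and the genes did not settle it: deviations of same-numbered arrays correlated at -0.20 to 0.36 over genes, and the best partner bore the same number for 3 of 6. With the replicate block the array level differed by 0.998, with the aged array higher in 6 of 6 pairs (exact sign-flip p = 0.031, the smallest 6 pairs allow), and the reference genes by 0.427 (exact sign-flip p = 0.031). The block leaves out young replicate 7, the young array of highest level, which has no same-numbered aged array. Over complete pairs the mean difference is the same with or without pairing. The moves from 0.80 to 0.998 and from 0.36 to 0.427 thus come from leaving out that array. The mean shift of Gapdh and Rpl13a, 0.36, was 0.37 with median centring (exact permutation p = 0.21), 0.24 without young replicates 1 and 2, -0.10 with quantile normalization, -0.45 with centring on the 15 probes, and 0.29 to 0.43 with 1 array left out. The array level difference ran from 0.563 to 0.998 with 1 array left out, with p under 0.05 in 4 of 13 cases. Casp8, near 0, turned to -0.21 with reference centring, -0.19 with quantile normalization, -0.012 on linear values, -0.77 with the 15 probes, and ran from -0.21 to 0.28 with 1 array left out. With blanks at 0.01, Cd27 turned to 0.31, Cflar to 0.065 and probe 2 to -0.32; with the 15 probes, Tnfrsf21 turned to -0.027, Bik to -0.027, Casp6 to -0.065 and probe 2 to -0.11. Tnf kept its direction in 26 of 26 alternatives on the log2 scale that tested it, from 1.25 to 2.44, and passed in 12. The cause of these changes was not tested. The smaller pseudocount was not run, as no value was 0 or below. Dim probes carry the blanks and the rounding, so their differences are the least certain.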

Other observations

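The genes of the 8 ratios were chosen, and both tests over all 105 ratios were added, after values had been seen; the count of splits for blanks was planned before its result was seen. The relation of 2 genes on the same array does not involve beta-actin. Of 8 such ratios compared by exact two-sided permutation tests, 1 passed: Lta, a ligand, rose 1.80-fold relative to Tnfrsf1b, a receptor of the same family (log2 difference 0.84, 95% interval 0.55 to 1.13, adjusted p = 0.0047). Tnf relative to Tnfrsf1b was 3.25-fold higher in aged arteries (log2 difference 1.70, interval 0.17 to 3.23, adjusted p = 0.11), and Casp9 relative to Casp2 was 1.64-fold higher (adjusted p = 0.38). Bcl2 relative to Bik, a protector against a killer of the same family, was 1.30-fold higher (interval of the log2 difference -0.43 to 1.19, adjusted p = 0.46).

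A hypothesis is that the genes of the array change by the same factor, as an error in beta-actin would produce, so that no ratio of genes differs between the groups. Over all 105 ratios of the 15 complete probes, the Benjamini-Hochberg adjustment could not decide, since the smallest exact p that 13 arrays allow, 0.00058, becomes 0.0612 for a lone ratio; 0 ratios passed it. The largest t statistic over the 105 ratios, that of Lta over Tnfrsf1b, was equalled or exceeded in 5 of all possible splits of the arrays, the real one included (exact permutation p = 0.0029), and it was the 1 ratio past 0.05 on this scale. This argues against a single factor for all genes as the whole difference, and does not show which of the 2 genes changed.

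Blank cells were compared as a readout of their own. Gene probes without a value numbered 29.5 ± 8.7 on aged and 35.6 ± 7.8 on young arrays (SD, n = 6 and 7, exact permutation p = 0.21). For 2 probes the share of arrays with a value differed at Fisher's exact p under 0.05, Tnfsf12 and the unnamed probe 20 (6 of 6 aged and 2 of 7 young arrays), and 38 of 100 splits of the arrays gave as many, with up to 6 in another split.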
